A study of Eublepharis macularius with 18 samples.

How the data were processed

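Ventricle RNA from 18 leopard geckos was sequenced, with 3 animals in each of 6 groups: control, sham-operated, and 3, 14, 30 and 100 days post injury. RNA was extracted separately from each animal, so the replicates are separate animals. The labels give no sampling time for the sham group and no sequencing batch. Per the submitters' processing notes, the tools were HISAT2 2.2.0, StringTie 2.2.1 and Salmon 1.8.0: reads were aligned to a leopard gecko genome, transcripts were assembled de novo and annotated with mouse genes. Rows therefore carry mouse Ensembl gene identifiers and mouse symbols, as the deposited tables give them.

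The authors deposited a table of normalized counts, a read signal per gene and library, with 12376 rows, of which 444 were at 0 in all 18 libraries. How that table was normalized is not stated in the sources used here. In each library every value was a whole multiple of 1 step, within 0.1 of a read (0 values were not whole), so whole read counts were recovered from the deposited normalized counts by dividing by the step. The reciprocals of the steps, the size factors of the table, equalled median-of-ratios size factors to within 1.89e-08%. The authors also deposited an FPKM table (fragments scaled by transcript length and by library total), used here as an alternative. The ratio of normalized count to FPKM was used as a measure of transcript length. Deviations of its log2 values from each gene's mean over libraries had an SD across genes of up to 0.104 within a library. Single genes may vary more between libraries.

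The libraries held 12646411 to 34898541 recovered reads. A floor of 3 reads per library corresponded to 1.45 to 3.95 normalized counts, and this floor covers counting error only, since the reads carry no molecular identifiers. Pairs of libraries within a group had Pearson r from 0.9476 to 0.9756 across genes and chi-square over degrees of freedom from 24.35 to 92.12, so no pair within a group was a copy; pairs across groups were not compared in this way.

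The following were fixed before the data were examined: the groups, the 12 comparisons, the tests, the gene lists, the rule for named genes and most of the other settings tried. Genes with a mean of at least 10 normalized counts over the 18 libraries were tested (9887), and 2489 rows were left out. log2(normalized count + 1) values of all 6 groups entered 1 limma model (limma-trend, limma 3.58.1 in R 4.3.3, two-sided, 12 residual degrees of freedom, prior df 3.611) with no block for replicate number. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. An exact permutation test of 3 animals against 3 cannot go below a p of 0.1, so calls for single genes rest on the model. Its spread for a gene comes mostly from that gene over all 6 groups (12 residual degrees of freedom). A smaller part is pooled across genes (prior df 3.611). The model takes the spread of a gene to be equal in all groups. Of 42 gene lists fixed for cell types, pathways and complexes, the 39 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data. The 3 lists under that minimum, for T cells, B cells and liver, lung and skin genes, had 4, 2 and 3 measured members and were not tested. Adjusted p-values were also computed over the members of each list alone. Lists were tested against control and between consecutive times, and not against sham.

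The text names members of the fixed lists. For each time after injury against control it names up to 12 of the largest rises and 8 of the largest falls among genes called in the same direction against control and sham, filled up by the smallest p against control. For sham against control and for steps between times it names up to 10 genes in each direction by the smallest p. Only genes with a mouse-style symbol were named, and where several rows carried 1 symbol the row with the highest mean was used. Any other gene is said to have been chosen after its values were seen. Some results that fall under this rule are not reported here.

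The other settings fixed in advance were pseudocounts of 0.1 and 10, no filter on low genes, TMM factors (edgeR 4.0.16), median-of-ratios factors, the FPKM table (pseudocount 0.1, minimum mean 0.5), only the 2 groups compared in the fit, the replicate number as a block, edgeR's quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, camera on the recovered reads, and each library left out in turn. Median-of-ratios factors equalled the deposited ones and so moved nothing. Chosen after seeing the data were the removal of each library's trend of log2 deviation on log2 transcript length (loess) and the thinning of every library to the smallest read total. The comparisons of 10 splits of 3 against 3 libraries used the same model. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

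The model was tested on simulated counts for 3 dpi against control with 9885 genes. It called 8 of 50 genes changed 1.5-fold (16%), 28 of 50 changed 2-fold (56%), 42 of 50 changed 4-fold (84%) and 49 of 49 changed 8-fold (100%), with 11 false calls among 9686 unchanged genes. In simulated 14 dpi against control, 0 of 390 random lists were called. The genes were simulated independently of each other, so this does not show how often lists are called when their genes vary together.

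No genome sequence was used here, so GC content was not checked. A reference gene table of assembly MPM_Emac_v1.0 shared a symbol with 10954 of the 12376 rows (88.51%), but the submitters name the build MPM_Emav_v1.0 and the rows are matched by symbol only, so no chromosome or position is given. Genes with close relatives, such as the globins, keratins and the complement proteases C1rb and C1s1, are uncertain where reads of near-identical copies were divided between rows or where mouse names were given to other members of a gecko family.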

Results

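RNA from the ventricle of the leopard gecko (Eublepharis macularius), a lizard, was compared after cryoinjury, in which a probe chilled with liquid nitrogen freezes part of the heart wall. Poly-A RNA was sequenced from 18 animals in 6 groups of 3: controls, sham-operated animals, and animals sampled 3, 14, 30 and 100 days post injury (dpi). The tissue came from beside the injury, or from a comparable part of the ventricle in control and sham animals. The libraries held between 12646411 reads (14 dpi 2) and 34898541 reads (100 dpi 3), and the next deepest held 19825686 reads (control 3). Levels below are normalized counts as mean ± SD (n = 3 animals), and log2 fold changes with their SE are on the log2(normalized count + 1) scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 by limma over 9887 tested genes, and gene lists fixed in advance were tested with camera in limma. Along the first principal component, which held 19.9% of the variance, the libraries of 30 and 100 dpi lay between 23.8 and 30.5 and all others between -47.1 and 2.72. Lars2, named after its values were seen, took 3.52% to 5.90% of reads in the control, sham, 3 and 14 dpi libraries. It took at least 8.25% at 30 dpi, with the highest share in 30 dpi 2, and 6.91% to 7.58% at 100 dpi. Whether all reads of this row come from that gene was not tested, so a wrongly named row stays possible.

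**Figure D1:**
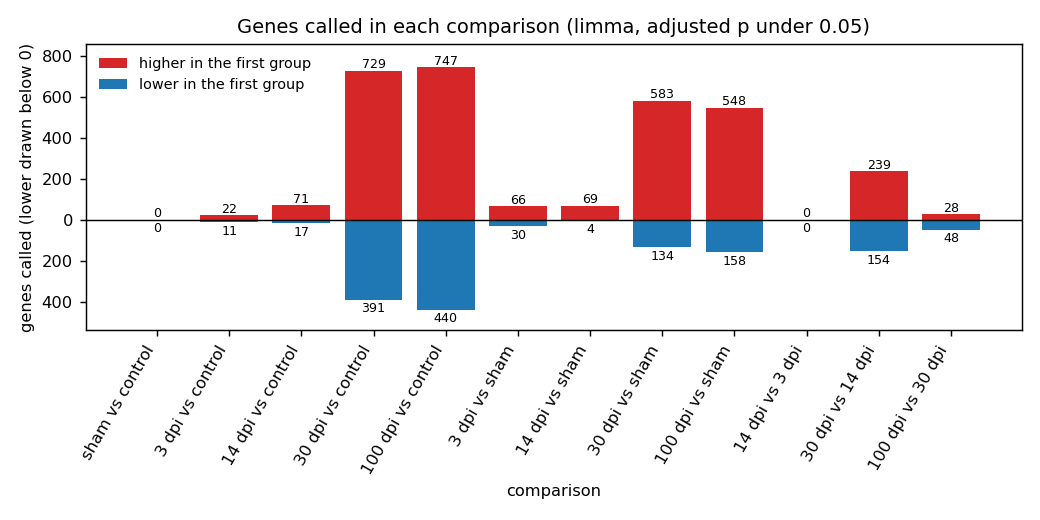
Number of genes called by limma in each of the 12 comparisons (bars above 0, higher in the first-named group; bars below 0, lower in it). Sham against control had 0 calls, and 30 and 100 dpi against control had 1120 and 1187.

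Sham hearts were set against control hearts to see what differed after the operation without freezing. Cell division genes were higher as lists in sham hearts. All 24 measured members of the mitosis and cytokinesis list had positive changes (median log2 1.67, camera adjusted p = 4.98e-10). The S phase and replication list had a median of 0.54 (adjusted p = 4.72e-07). With an estimated correlation both calls were lost (adjusted p = 0.567 for each list). Mitosis library medians in sham were -0.70, 0.30 and 2.21 on the log2 scale against -1.25 to -0.79 in control, so sham 3 stood apart. Immediate early genes, which respond within minutes to stimuli, were lower as a list in sham (median -1.14, adjusted p = 5.82e-14; adjusted p = 0.14 with an estimated correlation). The test called 0 of 16 members over all genes and 7 when adjusted over the list alone. Nr4a1, a nuclear receptor of this class, measured 4663 ± 1565 in sham and 21045 ± 3358 in control (log2 -2.21 ± 0.391 SE, limma adjusted p = 0.0796). Fosb, an AP-1 subunit, measured 31.4 ± 30.8 and 553 ± 451 (log2 -4.22 ± 0.961 SE, limma adjusted p = 0.291). Cytosolic ribosomal proteins (median -0.22), heat shock and unfolded protein response (-0.34), fatty acid oxidation (-0.17) and erythrocyte and thrombocyte genes (-0.73) were also lower as lists, with adjusted p between 1.31e-10 and 0.00309. These 4 calls were lost as well (adjusted p = 0.636 for ribosomal proteins and adjusted p = 0.567 for the others, with an estimated correlation).

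No single gene was called between sham and control. limma gave 0 genes, with 479 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0573, edgeR gave 0 and DESeq2 29. The count was 6 without control 1, 1 without control 2 and 1 without sham 3. The erythrocyte and thrombocyte call was lost without control 1 (adjusted p = 0.301) or sham 2 (adjusted p = 0.22), and the fatty acid oxidation call without control 3 (adjusted p = 0.0563).

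At 3 dpi against control, the first days after freezing, several genes known from neurons and from the extracellular matrix rose, as did the epithelial cadherin gene Cdh1. Nefl (ENSMUSG00000022055), the light neurofilament subunit of axons, measured 120 ± 39.7 against 2.92 ± 3.03 in control (log2 5.29 ± 1.07 SE, limma adjusted p = 0.049). Stmn2, a microtubule regulator of growing neurites, was at 53.2 ± 12.9 against 2.32 ± 1.58 (log2 4.11 ± 0.757 SE, limma adjusted p = 0.0376). Scg2, secretogranin II of secretory granules, was at 74.6 ± 47.9 against 0.336 ± 0.581, where the 3 controls held 1 read in all (limma adjusted p = 0.0339). Cdh1 rose 4.04-fold (373.6 ± 232.4 against 82.7 ± 17.6, limma adjusted p = 0.0339). C8a, a subunit of the membrane attack complex of complement, rose 5.10-fold (83.6 ± 11.5 against 15.6 ± 2.29, limma adjusted p = 0.0341). Col12a1, a collagen that binds to fibrils, rose 5.47-fold (log2 2.45 ± 0.423 SE) and Sparc, a collagen-binding matrix protein, 1.79-fold (11906 ± 2240.4 against 6586 ± 246), each at a limma adjusted p of 0.0339. Among genes that fell, Usp28, a deubiquitinase, measured 3041 ± 426 against 5974 ± 32.9 (log2 -0.98, limma adjusted p = 0.0206), Naa10, an amino-terminal acetyltransferase, changed by -0.94, and Cnn1, the smooth muscle calponin, by -0.96. Cnn1 was called against control only, and against sham it was at log2 0.09 (limma adjusted p = 0.815). In each of these genes all 3 libraries lay on one side of all 3 controls, which chance gives for 1 in 10 unchanged genes.

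Among the fixed lists at 3 dpi, all 31 measured fibrillar collagen and matrix genes had positive changes (median log2 0.96, camera adjusted p = 5.01e-13). Over all genes 2 members were called, Col12a1 and Sparc, and 18 when adjusted over the list alone, and the list call was lost (adjusted p = 0.17 with an estimated correlation). Of the 14 genes of the Schwann cell and neuron list 13 had positive changes (median 0.77, adjusted p = 1.72e-05; adjusted p = 0.151 with an estimated correlation), with 2 called, Nefl and Stmn2, and 6 adjusted over the list alone. The epicardium and mesothelium list was higher (median 1.09, adjusted p = 0.000301; adjusted p = 0.158 with an estimated correlation), with 1 of 11 called, Cdh1, and 3 adjusted over the list alone. Its members Krt18 and Krt8, keratins of simple epithelia, did not pass the test (limma adjusted p = 0.136 and 0.263), and Krt18 stood at 345, 243 and 2390 in the 3 libraries. Complement and coagulation genes were higher (median 1.08, adjusted p = 0.000669; adjusted p = 0.0913 with an estimated correlation), with 1 of 9 called and 5 adjusted over the list alone. Basement membrane genes (median 0.52, adjusted p = 6.38e-06; adjusted p = 0.267 with an estimated correlation) had 0 of 18 called and 7 adjusted over the list alone. Smooth muscle and pericyte genes had a median of 0.53 (adjusted p = 0.00513; adjusted p = 0.158 with an estimated correlation), with Cnn1 the 1 member called, downward.

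Ribosomal proteins (median -0.36, adjusted p = 4.69e-13), immediate early genes (-1.05, adjusted p = 4.22e-05) and interferon response genes (-0.65, adjusted p = 0.0127) were lower at 3 dpi with 0 members called. With an estimated correlation they gave adjusted p = 0.525, adjusted p = 0.303 and adjusted p = 0.607. Ribosomal and immediate early genes were also lower in sham against control (medians -0.22 and -1.14), and lists were not tested against sham. Glycolysis (median 0.40), fibroblast (0.35), endothelium (0.28) and lymphatic genes (0.73) were higher, with adjusted p from 0.0208 to 0.0378. They gave adjusted p = 0.607, adjusted p = 0.432, adjusted p = 0.546 and adjusted p = 0.504 in that order with an estimated correlation. Without 3 dpi 3 the glycolysis (0.133), fibroblast (0.217) and endothelium (0.241) calls were lost. So were, without control 1, the calls of glycolysis (0.0993), fibroblast (0.0648), endothelium (0.154) and interferon genes (0.05), without control 2 that of glycolysis (0.112), and without control 3 that of fibroblast genes (0.0515). The lymphatic call was lost without control 3 (0.334), 3 dpi 1 (0.16) or 3 dpi 2 (0.118), and the interferon call without 3 dpi 2 (0.0791). The lists of sarcomere, calcium handling and fetal cardiomyocyte genes had medians of 0.0035, 0.07 and 0.36 and were not called.

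**Figure D2:**
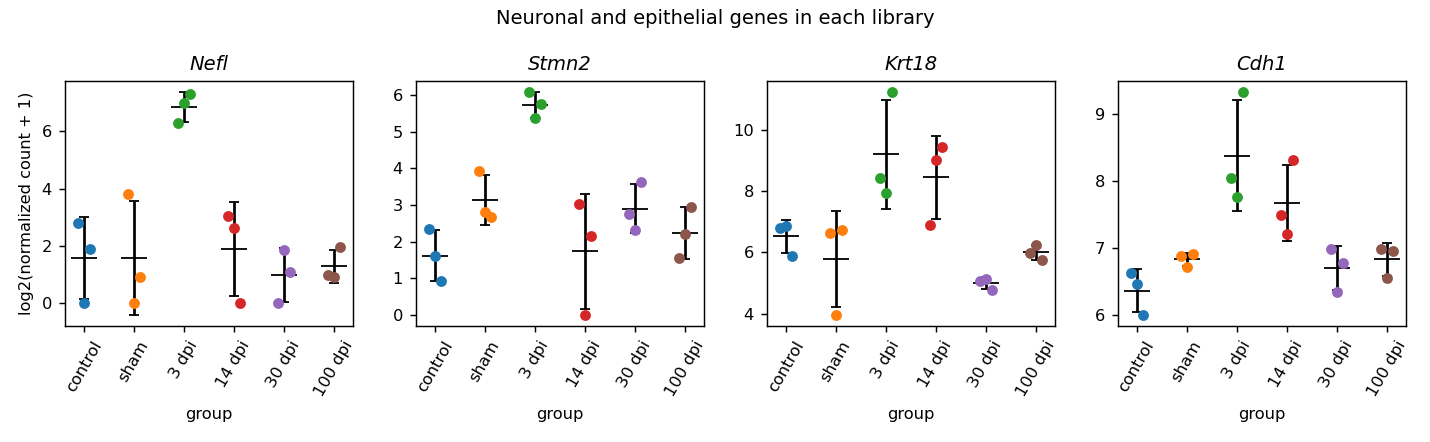
Normalized counts of Nefl, Stmn2, Krt18 and Cdh1 on a log2(normalized count + 1) axis, with 1 point per animal and the mean ± SD of the log2 values in each of the 6 groups. Nefl and Stmn2 lay above every other library in all 3 libraries at 3 dpi, while Krt18 and Cdh1 were highest in 3 dpi 3.

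In all, limma called 33 genes between 3 dpi and control, 22 higher and 11 lower. With TMM factors the split was 22 higher and 20 lower, and with each library's trend on transcript length removed, a setting chosen after seeing the data, 31 and 78. Against sham it called 96, 66 higher and 30 lower (85 and 117 with the length trend removed). Called against both were 19 genes in the same direction, where lists drawn independently would share 0.147 higher and 0.0334 lower genes. Simulated groups with no effect shared 0, but hardly any gene is called there, so this 0 does not measure what shared libraries add. Part of the excess may come from the shared 3 dpi libraries. These counts changed when 1 library was left out, which also lowers the number of animals. For 3 dpi against control there were 2, 1 and 11 genes without control 1, 2 and 3. Without 3 dpi 1, 2 and 3 there were 4, 87 and 1. Against sham there were 23, 2 and 6 without sham 1, 2 and 3, 7 without 3 dpi 1 and 4 without 3 dpi 3. Of the 20 genes named by rule, Zcchc24 was the 1 called in all 6 left-out fits, and 4, among them Nefl, were called in 0. With only the 3 dpi and control libraries in the fit 0 genes were called, with a pseudocount of 0.1 Nefl, Stmn2 and Scg2 were not, and Nefl was also not called by edgeR. A pseudocount of 10 gave log2 3.31 for Nefl and 2.35 for Stmn2. The lymphatic call was lost without a filter on low genes and in the FPKM table.

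At 14 dpi against control, matrix genes gave most of the named rises. Col12a1 (ENSMUSG00000032332) reached 860 ± 119 against 74.8 ± 20.1 in control, an 11.6-fold rise (log2 3.54 ± 0.423 SE, limma adjusted p = 0.00114). Thbs2, a matricellular thrombospondin, rose 7.98-fold (211 ± 45.6 against 25.2 ± 2.74, limma adjusted p = 0.00722). Tnc, tenascin C of healing tissue, rose 4.88-fold (624.5 ± 119.9 against 133 ± 56.1, limma adjusted p = 0.0132), and Col8a1 5.86-fold (limma adjusted p = 0.0244). Aspn, a small leucine-rich proteoglycan, rose by 2.97 on the log2 scale (limma adjusted p = 0.00771), Ctsk, a collagen-degrading cathepsin, by 2.48 (limma adjusted p = 0.0168) and Mmp2, a gelatinase, by 1.36 (limma adjusted p = 0.0192). Outside the matrix, Zcchc24 rose 7.25-fold (limma adjusted p = 5.97e-05), Nbeal1 4.43-fold (limma adjusted p = 0.00114) and Cdh5, the cadherin of endothelial junctions, 2.98-fold (559 ± 118 against 187 ± 41.9, limma adjusted p = 0.00926). Genes named as lower than control did not pass against sham. Dusp1, a phosphatase induced by stress, fell by 2.85 on the log2 scale (limma adjusted p = 0.0483), Gadd45b by 1.44 (limma adjusted p = 0.0356) and Nfkbia, the inhibitor of NF-kappa-B, by 0.96 (limma adjusted p = 0.0381).

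The fibrillar collagen and matrix list at 14 dpi had 15 of 31 members called higher, 26 when adjusted over the list alone, and a median log2 change of 1.27 (camera adjusted p = 5.66e-26; adjusted p = 0.104 with an estimated correlation). Members such as Col1a2 (9717 ± 922 against 3244 ± 713) and Sparc (13328 ± 831 against 6586 ± 246) rose 3.03-fold and 2.02-fold. Basement membrane genes were higher (median 0.53, adjusted p = 1.01e-08; adjusted p = 0.312 with an estimated correlation), with 2 of 18 called, Col4a5 and Nid1, and 10 adjusted over the list alone. All 24 mitosis and cytokinesis genes had positive changes (median 2.62, adjusted p = 1.12e-12; adjusted p = 0.312 with an estimated correlation), with 0 called and 19 adjusted over the list alone. Cdk1, the mitotic kinase, measured 207 ± 129 against 10.6 ± 2.35 (limma adjusted p = 0.127). S phase and replication genes had a median of 0.81 with 12 called over the list alone (adjusted p = 7.66e-08; adjusted p = 0.312 with an estimated correlation). Genes of oxidative phosphorylation (median -0.22, adjusted p = 0.00047), fatty acid oxidation (-0.27, adjusted p = 0.000577) and the citric acid cycle (-0.25, adjusted p = 0.000118), which supply energy to heart muscle, were lower as lists, with 0 members called. With an estimated correlation they gave adjusted p = 0.475, adjusted p = 0.312 and adjusted p = 0.312. Ribosomal proteins (median -0.42, adjusted p = 6.16e-18) had 0 members called and 24 adjusted over the list alone, and immediate early genes (-1.11, adjusted p = 0.000372) had 2, Dusp1 and Gadd45b. Both calls were lost (adjusted p = 0.312 for each with an estimated correlation). In sham against control the mitosis and S phase lists were higher too (medians 1.67 and 0.541). Immediate early, ribosomal and fatty acid oxidation genes were lower there too (-1.14, -0.219 and -0.165), and lists were not tested against sham.

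Another 11 lists had adjusted p between 0.0059 and 0.0493 at 14 dpi. Those higher were epicardium (median 1.22), lymphatic (0.49), macrophage (0.41), fibroblast (0.28), smooth muscle (0.23), protease (0.19), crosslinking (0.16) and TGF-beta genes (0.13), and those lower were glycolysis (-0.11), heat shock (-0.14) and antioxidant genes (-0.15). None of these held with an estimated correlation, at adjusted p = 0.312 to adjusted p = 0.52. Other settings ended some of these calls: no filter on low genes those of protease (0.0623), antioxidant (0.0614) and TGF-beta genes (0.167, median 0.016), the FPKM table those of antioxidant (0.0521) and TGF-beta genes (0.0673), and only the 2 groups that of TGF-beta genes (0.0713). Thinning to the smallest library, chosen after seeing the data, ended those of macrophage and antioxidant genes (0.0565 each). All but the epicardium call also ended without at least 1 library, at adjusted p from 0.0523 to 0.423. Calls were lost without control 1 for macrophage, crosslinking, protease, fibroblast and antioxidant genes, without control 2 for macrophage, smooth muscle and antioxidant genes, and without control 3 for glycolysis, crosslinking, lymphatic, heat shock, antioxidant and TGF-beta genes. They were lost without 14 dpi 1 for glycolysis, macrophage, protease, antioxidant and TGF-beta genes, and without 14 dpi 2 for glycolysis, crosslinking, smooth muscle, heat shock and antioxidant genes.

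**Figure D3:**
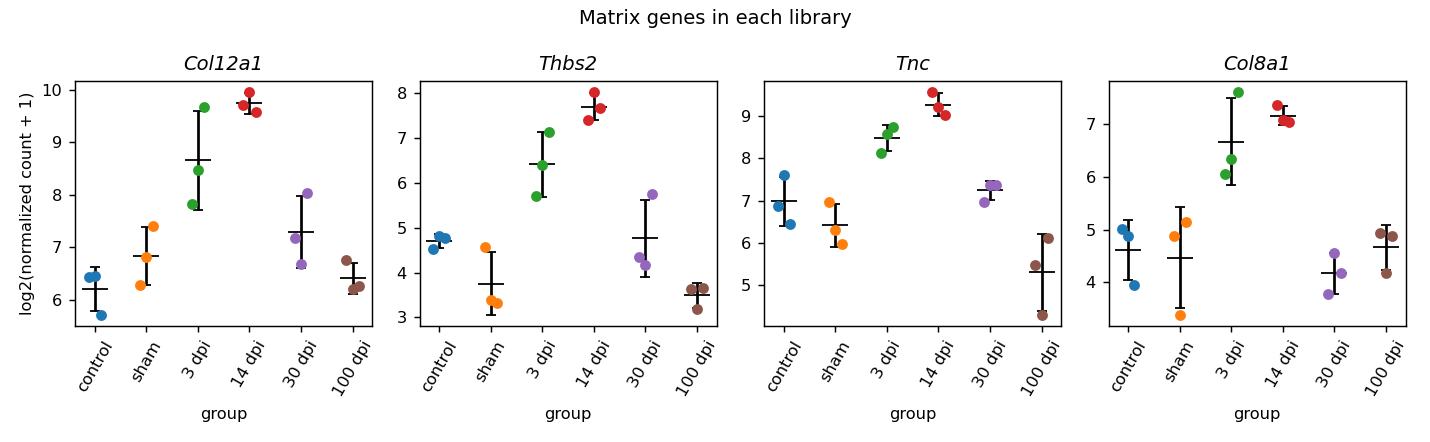
Normalized counts of the matrix genes Col12a1, Thbs2, Tnc and Col8a1 on a log2(normalized count + 1) axis, with 1 point per animal and the mean ± SD of the log2 values in each group. At 14 dpi the 3 libraries of each gene lay above all control and sham libraries, and by 30 dpi the group means were lower again.

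In the test over all genes limma called 88 between 14 dpi and control, 71 higher and 17 lower, and 73 against sham, 69 and 4. The same direction against both held for 38 genes, all higher, where independent lists would share 0.495 higher. Simulated groups with no effect shared 0, which again does not measure what shared libraries add. Part of the excess may come from the shared 14 dpi libraries. Leaving out 1 library gave 24, 27 and 25 genes against control without control 1, 2 and 3, and 11 and 5 without 14 dpi 1 and 14 dpi 2. Against sham there were 38 and 13 without sham 1 and 2, and 17 and 11 without 14 dpi 1 and 2; of the 20 genes named by rule, Col12a1, Nbeal1 and Zcchc24 were called in all 6 left-out fits and 8 in 0. Col8a1, Dusp1 and Nfkbia, named above, were called in 0. Nbeal1, Aspn, Mmp2 and Gadd45b were not called with only the 2 groups fitted, nor Nbeal1 in the FPKM table, and Dusp1 was not called by edgeR, in the FPKM table or without a filter on low genes. With the length trend removed, a setting chosen after seeing the data, 10 of the 15 called matrix genes were still called, and the glycolysis, antioxidant and TGF-beta list calls were lost. The matrix genes Fbln1, Lum, Col6a2, Fbn1 and Thbs1 were no longer called but moved by less than their SE (adjusted p from 0.0514 to 0.0704). The medians of glycolysis and antioxidant genes did not shrink (-0.14 and -0.18 against -0.11 and -0.15), and that of TGF-beta genes went from 0.13 to 0.025.

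Between 3 and 14 dpi, as lists, the neuronal genes were lower again and the cell division and matrix genes were higher. In the main analysis the cell division lists were not called at 3 dpi against control (adjusted p = 0.0955 for mitosis and 0.188 for S phase). The list of mitosis and cytokinesis was called there with only these 2 groups fitted (adjusted p = 0.0473), without 3 dpi 1 (0.00768), without 3 dpi 2 (0.0142) and with the length trend removed (0.019, a setting chosen after seeing the data), while without 3 dpi 3 its median was -0.10 (adjusted p = 0.698). All 14 Schwann cell and neuron genes had negative changes (median log2 -1.52, camera adjusted p = 1.88e-09), and this call held with an estimated correlation (adjusted p = 0.0342). Stmn2 measured 53.2 ± 12.9 at 3 dpi and 3.55 ± 3.59 at 14 dpi (log2 -4.00 ± 0.757 SE, limma adjusted p = 0.0783) and Gap43, a growth cone protein, 265 ± 165 and 38.7 ± 18.1 (limma adjusted p = 0.195). In all, 0 members were called over all genes and 6 when adjusted over the list alone. Mitosis (median 1.88, adjusted p = 2.33e-09), S phase (0.57, adjusted p = 6.41e-06) and matrix genes (0.54, adjusted p = 1.02e-06) were higher at 14 dpi, each at adjusted p = 0.452 with an estimated correlation. Lower were the lists of glycolysis (-0.43), fatty acid oxidation (-0.37), the citric acid cycle (-0.32) and oxidative phosphorylation (-0.31), with adjusted p between 3.73e-09 and 1.16e-05. These gave adjusted p = 0.306, adjusted p = 0.312, adjusted p = 0.288 and adjusted p = 0.452 with an estimated correlation. Complement (median -0.54, adjusted p = 0.016) and heat shock genes (-0.19, adjusted p = 0.00676) were lower and erythrocyte genes (0.42, adjusted p = 0.0171) higher. With an estimated correlation these gave adjusted p = 0.276, adjusted p = 0.599 and adjusted p = 0.599, and all 3 calls were lost without 3 dpi 3 (0.226, 0.558 and 0.0913). The complement call was also lost without 14 dpi 3 (0.0517), and the erythrocyte call without 3 dpi 1 (0.1) or 14 dpi 3 (0.192).

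No single gene was called between 14 and 3 dpi: limma gave 0, with 1205 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0517, edgeR gave 0 and DESeq2 92. Without 3 dpi 3 there was 1 gene.

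At 30 dpi against control the largest rises were in genes outside the matrix. Nbeal1 (ENSMUSG00000073664), a BEACH domain protein, measured 376.5 ± 63.4 against 12.5 ± 4.56, a 28.9-fold rise (log2 4.85 ± 0.261 SE, limma adjusted p = 2.26e-08). Zcchc24 (ENSMUSG00000055538), a zinc finger protein, was at 1190 ± 174 against 52.1 ± 16.6 (23.0-fold, limma adjusted p = 2.53e-08). Cbx6 and Cbx7, chromobox proteins of Polycomb complexes, rose 20.7-fold and 9.30-fold (limma adjusted p = 1.49e-05 and 9.27e-06). Rcan2, a calcineurin regulator, rose 20.6-fold, Unc5b, a netrin receptor of vessels and axons, 19.8-fold, and Agtr1b, an angiotensin II receptor, 13.4-fold, with limma adjusted p between 4.06e-06 and 5.67e-06 for these 3. Cdh5 rose 3.98-fold (750 ± 199 against 187 ± 41.9, limma adjusted p = 0.000191), Fgf2 2.84-fold (limma adjusted p = 0.00134). Cldn5, another endothelial gene, was lower (log2 -2.00 ± 0.492 SE, limma adjusted p = 0.0163, but 0.065 with the length trend removed). The endothelium list was not called. Nrg1, a growth factor for heart muscle cells, rose 2.53-fold (limma adjusted p = 0.017) and Ttn, the giant sarcomere protein, 2.11-fold (limma adjusted p = 0.00117). Lower were Clu, the secreted chaperone clusterin (5162 ± 717 against 11556 ± 1828, log2 -1.16, limma adjusted p = 0.00387) and Mdk, the growth factor midkine (log2 -1.27, limma adjusted p = 0.0143). So were Col20a1 (log2 -2.89, limma adjusted p = 0.00198) and Cnn1 (log2 -1.29, limma adjusted p = 0.000371). Cnn1 was called lower against control but not against sham. Mylk and Abcc9, genes of smooth muscle and pericytes, were higher against control (log2 1.04 and 1.07, limma adjusted p = 0.014 and 0.0233). With the length trend removed their adjusted p was 0.0916 and 0.117. Pvalb, parvalbumin of fast muscle, had 0 reads in all 3 libraries against 72.9 ± 28.3 in control, at least 20.2-fold lower at a floor of 3 reads per library (limma adjusted p = 0.0193). It was also at 0 in sham 2, sham 3, 14 dpi 1 and 14 dpi 3.

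Fibrillar collagen and matrix genes at 30 dpi had a median of 0.19 and were not called as a list (camera adjusted p = 0.491), with Col5a2 the 1 of 31 called. Cytosolic ribosomal protein genes were lower: 17 of 41 were called, 37 when adjusted over the list alone, and the median was -0.47 (adjusted p = 1.01e-13; adjusted p = 0.87 with an estimated correlation). Rpl3 measured 5971 ± 1159 against 10350 ± 713 (log2 -0.81, limma adjusted p = 0.00599). Heat shock genes (median -0.33, adjusted p = 0.00736) had 3 members lower, among them Hsp90aa1 (log2 -1.16), and 1 higher, Sel1l, and antioxidant genes (-0.32, adjusted p = 0.00655) had 2 lower, Prdx2 and Gsr. Oxidative phosphorylation genes (-0.24, adjusted p = 0.00655) were lower as a list, and immediate early genes (-0.93, adjusted p = 0.0413) had 3 lower, Jun, Jund and Gadd45b. With an estimated correlation these 4 lists gave adjusted p = 0.87, adjusted p = 0.87, adjusted p = 0.879 and adjusted p = 0.879. Ribosomal, heat shock and immediate early genes were also lower in sham against control (medians -0.219, -0.344 and -1.14). Whether these lists differed from sham at 30 dpi was not tested. Lymphatic genes were higher (median 0.62, adjusted p = 0.0413; adjusted p = 0.87 with an estimated correlation), with 2 of 8 called, Prox1, the regulator of lymphatic identity (2.27-fold), and Stab1 (1.65-fold). Without 30 dpi 3 the calls of oxidative phosphorylation (0.363), lymphatic (0.228), heat shock (0.0874) and antioxidant genes (0.138) were lost. Lost without control 3 were those of oxidative phosphorylation (0.0624), lymphatic (0.173), heat shock (0.0532) and immediate early genes (0.173). The immediate early call was also lost without 30 dpi 1 (0.141), and without 30 dpi 2 both it (0.165) and the lymphatic call (0.113) were. Receptors of TGF-beta and BMP signalling rose without a list call: Tgfbr1, Tgfbr3, Bmpr1a and Bmpr2 were 4 called members, with Bmpr1a at log2 0.81 ± 0.095 SE (limma adjusted p = 8.77e-05).

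Transcript length moved with these groups (the values follow with the counts). With each library's length trend removed, a setting chosen after seeing the data, the ribosomal list was the 1 list still called of the 6 (median -0.18, camera adjusted p = 0.000547), with 16 of its 17 called genes no longer called and Rpl3 kept. Lost with smaller medians were the list calls of oxidative phosphorylation (-0.24 to -0.076, adjusted p = 0.408), antioxidant (-0.32 to -0.13, adjusted p = 0.171) and lymphatic genes (0.62 to 0.43, adjusted p = 0.153). Heat shock and immediate early genes kept about the same medians (-0.30 and -0.85 against -0.33 and -0.93) at an adjusted p of 0.0521 each. Among single genes that lost their call, Ttn went from log2 1.08 ± 0.176 to 0.51 ± 0.184 SE, Bmpr2 from 0.61 ± 0.137 to 0.21 ± 0.149, and Prox1 from 1.18 ± 0.259 to 0.82 ± 0.257. Tgfbr3, Col5a2 and Sel1l also shrank, to 0.53, 0.42 and 0.29. Bmpr1a and Stab1 were still called but went from 0.81 to 0.45 and from 0.73 to 0.44. Jun, Jund and Gadd45b moved by less than their SE (-1.16 ± 0.321, -0.97 ± 0.292 and -1.19 ± 0.289 before).

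limma called 1120 genes between 30 dpi and control, 729 higher and 391 lower, and 717 against sham, 583 and 134. Against both, 556 genes went the same way, where independent lists would share 43 higher and 5.30 lower. Simulated groups with no effect shared 0, which does not measure what shared libraries add. Part of the excess may come from the shared 30 dpi libraries. Longer transcripts were higher at 30 dpi. Across genes, which are not independent replicates, Spearman's rho of transcript length with log2 fold change was 0.461. The median change was 0.24 in the 25% of genes with the longest transcripts and -0.26 in the 25% with the shortest. Removing each library's length trend (chosen after seeing the data) left 497 genes against control, 395 of them among the 1120, and 337 against sham. The count against control was 624 without control 2 and 592 without 30 dpi 3, and against sham 379 without sham 2 and 461 without 30 dpi 3. There were 2 lists without control 3 or without 30 dpi 3. Of the 6 left-out fits, Col5a2 and Tgfbr1 were called in 1, Jun and Jund in 2, Gadd45b and Pvalb in 3, Mdk in 4, and Nrg1 and Bmpr2 in 5. With only the 2 groups fitted there were 405 against control and 281 against sham, and Nrg1, Hsp90aa1, Tgfbr1, Tgfbr3, Col5a2, Jun, Jund and Gadd45b were not called; Pvalb was not called by edgeR or DESeq2. In the FPKM table the immediate early list call was lost (adjusted p = 0.0534), and a pseudocount of 10 gave log2 -1.27 for Col20a1.

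From 14 to 30 dpi matrix and fibroblast genes fell, and cell division genes were lower as lists. Tagln, the actin-binding protein of myofibroblasts and smooth muscle, fell from 454.5 ± 321.1 to 6.46 ± 4.76 (log2 -5.86 ± 0.836 SE, limma adjusted p = 0.00177). Col8a1 fell by 3.00 on the log2 scale (limma adjusted p = 0.0039), Thbs2 by 2.94 (limma adjusted p = 0.00294), Col12a1 by 2.45 (limma adjusted p = 0.00602) and Sparc by 1.19 (13328 ± 831 to 5859 ± 659, limma adjusted p = 0.000848). Mdk fell by 1.89 and Fstl1, a secreted glycoprotein of epicardium and fibroblasts, by 1.00 (limma adjusted p = 0.0039 and 0.00477). Genes that rose were Cbx7 (log2 3.35 ± 0.301 SE, limma adjusted p = 4.5e-05), Nbeal1 (2.71, limma adjusted p = 5.25e-05), Lifr, the LIF receptor (1.68, limma adjusted p = 8.72e-05), and Pde3a, a cardiac phosphodiesterase (5141 ± 1580.2 against 1149 ± 64.2, limma adjusted p = 0.00109).

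Of the 31 matrix genes 13 fell from 14 to 30 dpi, 23 when adjusted over the list alone (median log2 -1.13, camera adjusted p = 2.05e-19; adjusted p = 0.268 with an estimated correlation). S phase genes were lower (median -0.99, adjusted p = 4.36e-10; adjusted p = 0.341 with an estimated correlation), with 4 of 28 called, the replicative helicase subunits Mcm3, Mcm4, Mcm5 and Mcm6, and 14 adjusted over the list alone. All 24 mitosis genes had negative changes with 0 called (median -2.01, adjusted p = 3.56e-08; adjusted p = 0.621 with an estimated correlation). Fibroblast genes had 4 of 20 called lower, Dpt, Tagln, Lrrc15 and Mfap4, and 8 adjusted over the list alone (median -0.47, adjusted p = 0.000308; adjusted p = 0.305 with an estimated correlation). Epicardium genes (median -0.47, adjusted p = 0.00255; adjusted p = 0.341 with an estimated correlation) had 2 called, Krt8 and Krt18 (log2 -3.70 and -3.46). Erythrocyte genes (median -0.84, adjusted p = 0.00757; adjusted p = 0.621 with an estimated correlation) had 2 lower, the globins Hba-a1 (log2 -2.95) and Hbb-y (-3.13), and 1 higher, Sptb. Crosslinking genes (median -0.32, adjusted p = 0.00255; adjusted p = 0.341 with an estimated correlation) had 2 called and basement membrane genes (-0.26, adjusted p = 0.0102; adjusted p = 0.621 with an estimated correlation) 3. The basement membrane call was lost without 14 dpi 1 (0.0848) or 30 dpi 1 (0.389).

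limma called 393 genes in this step, 239 higher at 30 dpi and 154 lower, and 214 with the length trend removed (chosen after seeing the data). There were 142, 168 and 150 without 14 dpi 1, 2 and 3, 224 without 30 dpi 2 and 184 without 30 dpi 3, which also gave 13 lists in place of 8. All 20 genes named by rule were called in each left-out fit. The list members named above did worse: Mcm3, Mcm5 and Mcm6 were called in 0 of the 6 fits, Krt18 and Dpt in 1, Krt8, Hba-a1 and Hbb-y in 2, Sptb in 3 and Mcm4 in 4. With the length trend removed all 8 list calls were kept among 14, as were 11 of the 13 matrix calls, while 8 of the list members named above were no longer called. Of these, Mcm3, Mcm5, Mcm6, Krt18, Hba-a1, Hbb-y and Dpt moved by less than their SE. Mcm3 went from log2 -3.17 ± 0.778 to -3.10 ± 0.775 SE and Hbb-y from -3.13 ± 0.761 to -2.88 ± 0.769, with adjusted p from 0.0501 to 0.119 over the 7 genes. Sptb went from 0.47 ± 0.104 to 0.22 ± 0.116. The matrix genes Lum and Cthrc1 also lost their calls but moved by less than their SE. Lum went from -1.13 ± 0.274 to -0.96 ± 0.29 and Cthrc1 from -2.76 ± 0.648 to -2.54 ± 0.653 (adjusted p = 0.0943 and 0.0557). With only the 2 groups fitted there were 177 genes, without Dpt, Hba-a1 and Sptb.

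**Figure D4:**
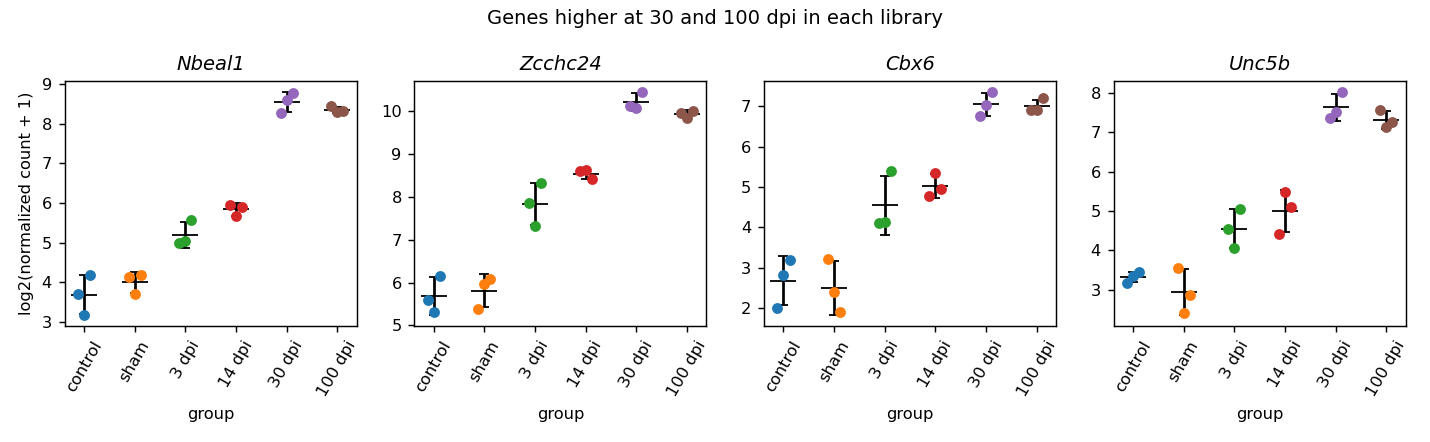
Normalized counts of Nbeal1, Zcchc24, Cbx6 and Unc5b on a log2(normalized count + 1) axis, with 1 point per animal and the mean ± SD of the log2 values in each group. In each gene the 3 and 14 dpi means lay between those of control and of 30 dpi, and all libraries of 30 and 100 dpi lay above all others.

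At 100 dpi against control the genes highest at 30 dpi were still high. Nbeal1 measured 326 ± 17.6 against 12.5 ± 4.56 (25.2-fold, log2 4.66 ± 0.261 SE, limma adjusted p = 4.18e-08), Cbx6 rose 20.1-fold, Zcchc24 19.0-fold, Unc5b 15.9-fold, Rcan2 13.5-fold and Agtr1b 12.3-fold. Among genes of endothelium, Cdh5 stood at 1049 ± 172 against 187 ± 41.9 (5.63-fold, limma adjusted p = 3.02e-05). Npr3, a natriuretic peptide receptor of endocardium, rose 1.98-fold (limma adjusted p = 0.0378) and Flt1, a VEGF receptor, 1.92-fold (limma adjusted p = 0.0212). Tnc was now below control (43.7 ± 24.9 against 133 ± 56.1, log2 -1.68, limma adjusted p = 0.0127). So were the homeobox genes Msx1 (log2 -3.74, limma adjusted p = 0.0185) and Prrx1 (-1.62, limma adjusted p = 0.0287) and the peripheral neurofilament gene Prph (-2.02, limma adjusted p = 0.0117). The cardiac transcription factors Nkx2-5 and Gata5 were lower by 0.59 and 0.51 on the log2 scale (limma adjusted p = 0.0184 and 0.00403), and Ttn was 1.87-fold higher (limma adjusted p = 0.00473). Mef2c, another cardiac transcription factor, was higher by 0.51 (limma adjusted p = 0.0242, but 0.14 with the length trend removed). The list of cardiac transcription factors was not called. Pvalb was again at 0 reads, at least 31.3-fold below control at a floor of 3 reads per library (limma adjusted p = 0.0192).

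Endothelium and endocardium genes were higher as a list at 100 dpi (median 0.49, camera adjusted p = 0.00886; adjusted p = 0.784 with an estimated correlation), with 4 of 18 called, Cdh5, Flt1, Nfatc1 and Npr3, and 7 adjusted over the list alone. Heat shock genes were lower (median -0.49, adjusted p = 0.00119; adjusted p = 0.784 with an estimated correlation), with 6 of 25 called, among them Hspb8 (log2 -1.12) and Bag3 (-0.77), and Sel1l higher. Citric acid cycle genes (median -0.30, adjusted p = 0.000341) had 2 called, Cs and Mdh2, and 9 adjusted over the list alone, and oxidative phosphorylation genes (-0.22, adjusted p = 0.00119) had called members that included Cyc1 and Atp5a1. Both were at adjusted p = 0.784 with an estimated correlation. Ribosomal protein genes (-0.25, adjusted p = 6.81e-05) had 1 called, Rpl15, antioxidant genes (-0.33, adjusted p = 0.0128) 1, Gsr, and fatty acid oxidation genes (-0.26, adjusted p = 0.048) Hadha lower and Ppara, a regulator of lipid burning, higher. These 3 lists were at adjusted p = 0.784 with an estimated correlation. Lymphatic genes had 2 of 8 called, Mmrn1 and Stab1 (median 0.50, adjusted p = 0.0476; adjusted p = 0.784 with an estimated correlation). Mitosis (median 1.34, adjusted p = 0.00886) and interferon response genes (0.82, adjusted p = 0.0247) were higher with 0 called, each at adjusted p = 0.784 with an estimated correlation. Both calls were lost without 100 dpi 3, to a median of 0.47 (adjusted p = 0.608) and 0.35 (adjusted p = 0.397), as were the fatty acid oxidation (0.171) and lymphatic calls (0.0544). The interferon call was also lost without control 2 (0.0705) or 100 dpi 2 (0.0934), the lymphatic call without control 3 (0.185) or 100 dpi 2 (0.0766) and the antioxidant call without 100 dpi 2 (0.0519). The fatty acid oxidation call was lost without control 1 (0.0506), control 3 (0.185) or 100 dpi 1 (0.0616). In sham against control mitosis genes were also higher (median 1.67). Heat shock, ribosomal and fatty acid oxidation genes were also lower there (-0.344, -0.219 and -0.165), and lists were not tested against sham.

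limma called 1187 genes between 100 dpi and control, 747 higher and 440 lower, and 706 against sham, 548 and 158. Against both, 576 genes went the same way, where independent lists would share 41.4 higher and 7.03 lower. Simulated groups with no effect shared 0, which does not measure what shared libraries add. Part of the excess may come from the shared 100 dpi libraries. The comparisons of 30 dpi against control and 100 dpi against sham have no library in common. They shared 354 higher and 13 lower genes (independent lists, 40.4 and 6.25), with 3 in opposite directions. Both used the same spread per gene from 1 model, and in both longer transcripts were higher (Spearman's rho across genes 0.461 and 0.232). The numbers for independent lists may therefore be too low. The count against control was 767 and 720 without control 2 and 3, 588, 784 and 784 without 100 dpi 1, 2 and 3. Against sham it was 395 and 348 without sham 1 and 2 and 411 and 427 without 100 dpi 1 and 2. With the length trend removed (chosen after seeing the data) there were 1069 genes against control, 771 of them among the 1187. In that setting Ttn (log2 0.90 ± 0.176 to 0.54 ± 0.184 SE), Npr3 (0.99 ± 0.289 to 0.68 ± 0.308) and Sel1l (0.48 ± 0.113 to 0.30 ± 0.111) were not called. Nor were Nfatc1, Cs, Mdh2, Cyc1 and Rpl15, which moved by less than their SE, with adjusted p from 0.0541 to 0.0805. The list calls of fatty acid oxidation (median -0.26 to -0.22, adjusted p = 0.188), lymphatic (0.50 to 0.30, adjusted p = 0.0841) and antioxidant genes (-0.33 to -0.22, adjusted p = 0.0841) were lost. Of the 6 left-out fits, Npr3, Nfatc1, Cs, Mdh2 and Cyc1 were called in 0, Rpl15 and Hadha in 1, Msx1 and Prrx1 in 2, Flt1, Nkx2-5 and Pvalb in 3, Mmrn1 in 4, and Tnc, Atp5a1, Gsr and Sel1l in 5. The fatty acid oxidation list call was lost in the FPKM table (adjusted p = 0.0582), and a pseudocount of 10 gave log2 -2.29 for Msx1 and -1.15 for Prph. Tnc, Prrx1, Hadha, Cs and Mdh2 were not called with only the 2 groups fitted, and Pvalb was not called by edgeR.

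From 30 to 100 dpi, single genes of granulocytes and complement rose, and the cytoskeletal gene Obsl1 was among those that fell. Mpo, myeloperoxidase of granulocytes, measured 22.0, 171 and 103 in the libraries of 100 dpi and 8.04, 6.59 and 5.72 in those of 30 dpi (log2 3.26 ± 0.629 SE, limma adjusted p = 0.0352). C1s1 and C1rb, proteases that start the classical complement pathway, rose 3.75-fold and 3.20-fold (limma adjusted p = 0.0352 and 0.029), and Unc93b1, which carries nucleic acid sensing receptors to endosomes, 1.61-fold (limma adjusted p = 0.029). Lower at 100 dpi were Obsl1, a cytoskeletal linker (5183 ± 561 against 11543 ± 2208, log2 -1.14, limma adjusted p = 0.0352), Rbpms2, an RNA-binding protein (-0.96, limma adjusted p = 0.029), and Tnc (-1.94, limma adjusted p = 0.0421).

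Interferon response genes were higher in this step, all 13 with positive changes (median log2 1.44, camera adjusted p = 4.76e-06; adjusted p = 0.772 with an estimated correlation), with 0 called and 8 adjusted over the list alone. Their library medians were -0.09, 1.18 and 1.82 at 100 dpi against -0.62 to -0.11 at 30 dpi. The neutrophil list was higher (median 2.00, adjusted p = 0.000776; adjusted p = 0.756 with an estimated correlation), with 1 of 6 called, Mpo, and 4 adjusted over the list alone. Endothelium genes (median 0.49, adjusted p = 0.000102; adjusted p = 0.756 with an estimated correlation) had 0 called and 2 adjusted over the list alone. Ribosomal protein (0.23, adjusted p = 4.2e-05), S phase (0.45, adjusted p = 0.0245) and mitosis genes (0.86, adjusted p = 0.0333) were higher with 0 called, and citric acid cycle genes (-0.12, adjusted p = 0.00581) lower with 1 called, Ogdh. These 4 lists were each at adjusted p = 0.85 with an estimated correlation. Without 100 dpi 3 the S phase (0.512) and mitosis (0.934, median -0.09) calls were lost, as they were without 30 dpi 1 (0.11 and 0.102) or 30 dpi 2 (0.0584 and 0.566). The citric acid cycle call was lost without 30 dpi 1 (0.102) or 30 dpi 2 (0.103), and the ribosomal call without 30 dpi 2 (0.0584) or 30 dpi 3 (0.0952).

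**Figure D5:**
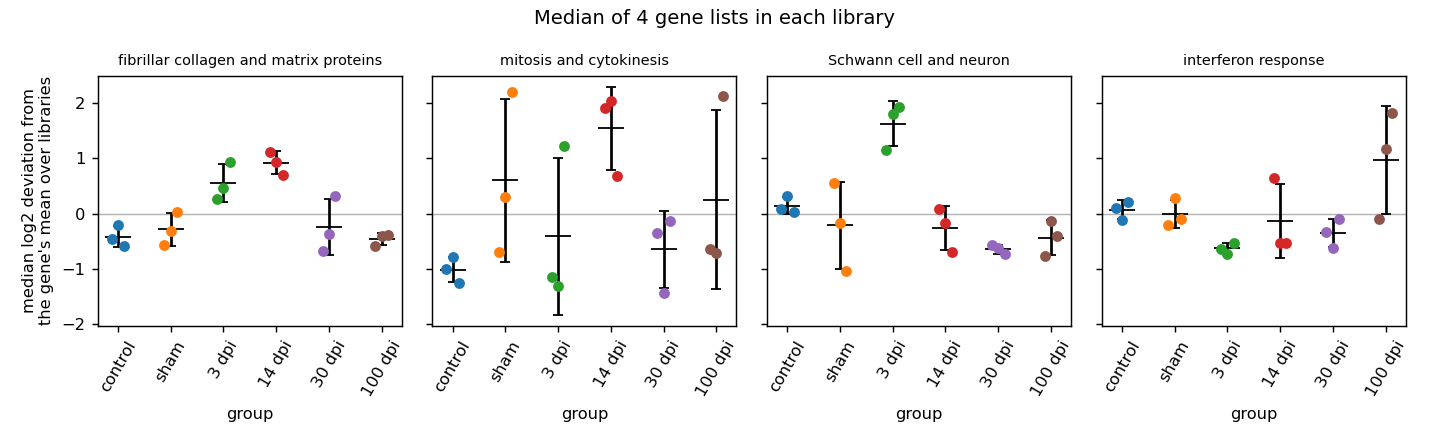
Median log2 deviation from each gene's mean over the 18 libraries, for 4 gene lists, with 1 point per animal and the mean ± SD in each group. The Schwann cell and neuron list was highest at 3 dpi and the matrix list at 3 and 14 dpi, while the mitosis list reached 2.21 in sham 3 and 2.12 in 100 dpi 3 and the interferon list 1.82 in 100 dpi 3.

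limma called 76 genes between 100 and 30 dpi, 28 higher at 100 dpi and 48 lower. There were 360 without 30 dpi 1, 1 without 30 dpi 2, 0 without 30 dpi 3, 44 without 100 dpi 1 and 0 without 100 dpi 2 or 100 dpi 3. There were 3 lists without 30 dpi 2. None of the genes named here was called in all 6 left-out fits. With only the 2 groups fitted there were 0 genes, and in the FPKM table Mpo and Tnc were not called and the S phase (adjusted p = 0.0501) and mitosis (adjusted p = 0.0507) list calls were lost. The ribosomal list call was lost with the length trend removed (median 0.23 to 0.036, adjusted p = 0.503), a setting chosen after seeing the data, and the mitosis call with TMM factors.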

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

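Chosen after the result was seen were the tests of a shared batch and of epithelium, the nerve list without genes seen before, and the length and thinning settings, and 6 nerve genes had been seen to be high before the list of nerve genes was written.

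Times after injury were compared by the test of the difference itself. Between 14 and 3 dpi 11 lists moved at the preset correlation and 1 at an estimated one, and 0 genes were called by limma (1205 at an unadjusted p under 0.05, edgeR 0, DESeq2 92). Between 30 and 14 dpi 393 genes were called (142 to 482 with 1 library left out), and 8 lists moved at the preset correlation and 0 at an estimated one. Between 100 and 30 dpi 76 genes were called (0 to 360 with 1 library left out), and 7 lists moved at the preset correlation and 0 at an estimated one. Other splits of the same libraries moved up to 14, 16 and 13 lists.

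Many more genes were called against control at 30 dpi (1120) and 100 dpi (1187) than at 3 dpi (33) and 14 dpi (88). Unequal depth was argued against, since thinning every library to the smallest left 1085 genes at 30 dpi, 1035 of them among the 1120. A bias toward long transcripts may account for part of the excess. Removing the length trend left 497 genes at 30 dpi (395 among the 1120) and 1069 at 100 dpi (771 among the 1187). The 497 lay between bounds that were set before that test but after the count of 1120 was seen. A batch shared by the 30 and 100 dpi libraries cannot be told apart from time after injury, because no label gives a batch; it could also underlie the 367 genes called in the same direction at 30 dpi against control and 100 dpi against sham, which have no library in common. A biological difference with time after injury stays open beside these.

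The list of nerve genes had 21 of 46 members measured at 3 dpi against control, 20 above 0, 3 called and 15 when adjusted over the list alone. Its median was 1.84, with library medians of 1.63, 1.73 and 2.42 against at most 0.131 in control. Of the 21, 14 are detected in control and 8 are also in the fixed lists. Among abundant members not called by limma, Dpysl3, the highest in control, went from 2954 to 2825 normalized counts (log2 -0.07, adjusted p = 0.92), Eno2 from 888 to 2855 (log2 1.72, adjusted p = 0.187), Ina from 1306 to 1797 (log2 1.84, adjusted p = 0.616) and Snap25 from 871 to 1177 (log2 0.42, adjusted p = 0.932). The epithelial list had 17 of 33 measured, 15 above 0, 1 called and 12 over the list alone, with a median of 2.07, library medians of 1.67, 1.13 and 3.64, and Dsp and Krt6a going from 4206 to 3001 and 101 to 1229 normalized counts. Of its 17, 12 are detected in control and 6 are in the fixed lists. Genes entered by their mean over all 18 libraries, so nerve and epithelial members low in control could enter by being high at 3 dpi. That selection can raise both medians and both counts above 0. The Schwann cell list had 10 of 20 measured, 0 called and a median of 0.353 (10 detected in control, 7 in the fixed lists). The leukocyte list had 16 of 25 measured, 0 called and a median of -0.0551 (16 detected in control, 5 in the fixed lists).

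Of the explanations for the higher nerve transcripts, Schwann cells in the same proportion as neurons were argued against. The Schwann cell median minus the nerve median was -1.49 on the log2 scale. This difference counts equally against added nerve tissue that brings Schwann cells in that proportion. The filter may have raised the nerve median and so widened the difference. More nerve or ganglion tissue in the sampled pieces, with Schwann cells below that proportion, is a candidate explanation. Without the 6 genes seen before and members of the fixed lists, 11 nerve genes had a median of 1.58 (10 above 0, 0 called). Dpysl3, the member highest in control, lay slightly lower. Genes low in control could pass the filter by being high at 3 dpi, so this median may be too high. Epithelium carried over in dissection stays open, because the nerve median was 1.62 without 3 dpi 3, the library with the highest epithelial median, but the epithelial list was high in the other 3 dpi libraries too. Against it, 14 dpi 2 and 14 dpi 3 had epithelial medians of 1.26 and 1.94 with nerve medians of 0.259 and 0.270, though tissue carried over at another time need not hold the same nerves. A response of the heart's own nerves to injury would raise the same genes, so the median does not tell it from more nerve tissue, and it stays open.

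Transcripts of mitosis were high in single libraries, with medians of 2.21 in sham 3, 1.23 in 3 dpi 3 and 2.12 in 100 dpi 3, where the other libraries of these groups lay between -1.31 and 0.295. All 3 carry replicate number 3, and the labels do not say what a shared number means. Control 3 and 14 dpi 3 were the lowest of their groups (-1.25 and 0.685), and 30 dpi 3 the highest of its group (-0.136). Depth was argued against as the source in 100 dpi 3, the deepest library, which still led its group by 2.72 after thinning. More blood cells could raise such transcripts and stay open, since the 95% interval of r is wide (-0.569 to 0.533) around r = -0.0258 with the globin median. More leukocytes stay open for the same reason (r = 0.281, 95% interval -0.319 to 0.72). Dividing cells of the heart in single animals stay open, as untested.

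Both correlations were computed within groups over 18 libraries with a permutation test of 100000 resamples, and the intervals of r come from Fisher's transformation. For globin the permutation p of r was 0.943, and rho was -0.127 (permutation p = 0.669). For leukocytes the permutation p of r was 0.488, and rho was 0.158 (permutation p = 0.634). The adjusted p of r over these 2 relations was 0.943 for both. Leaving out sham 3 and sham 2 gave r = -0.334 for globin, and leaving out 100 dpi 1 and 14 dpi 1 gave r = 0.165 for leukocytes.

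Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. Against control, the real count of genes and the highest of the other splits were 0 and 0 for sham, 33 and 1 for 3 dpi, 88 and 0 for 14 dpi, 1120 and 0 for 30 dpi and 1187 and 0 for 100 dpi. Against sham they were 96 and 0, 73 and 2, 717 and 0, and 706 and 0 for the same times. For the steps they were 0 and 0 for 14 against 3 dpi, 393 and 0 for 30 against 14 dpi and 76 and 3 for 100 against 30 dpi. For lists against control they were 7 and 11 for sham, 13 and 12, 20 and 12, 6 and 10, and 10 and 13 for the 4 times. For lists in the steps they were 11 and 14, 8 and 16, and 7 and 13. Splits with at least the real count of genes, the real one included, numbered 10 where that count was 0 and 1 elsewhere. For lists they numbered 4 for sham, 1, 1, 7 and 3 for 3, 14, 30 and 100 dpi against control, and 4, 6 and 6 for the steps.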

How the results depend on the processing

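Removing the transcript length trend and thinning to the smallest library were chosen after seeing the data; the other alternatives were planned. Of 5528 values of named genes under alternatives 4158 kept their direction and side of the threshold, 1370 kept the direction but no longer passed, and 0 reversed. Of 1312 list calls under alternatives at the preset correlation, 1200 were kept, 111 were lost and 1 turned without being called; the estimated correlation, counted apart, kept 1 list call and ended all others. Pseudocount 0.1, TMM factors and camera on recovered reads left every count they gave within 1.5 times, and median-of-ratios factors equalled the deposited ones and so tested nothing. The gene values and list calls under median-of-ratios factors are nevertheless counted as kept in both tallies above. DESeq2 gives no list test. Library depth limits low genes most: a floor of 3 reads was 1.45 to 3.95 normalized counts, and changes below it were not detectable. Except where fewer samples or genes entered the fit, the cause of the changes below was not tested.

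With an estimated inter-gene correlation the lists moved were 0 for sham, 3, 14, 30 and 100 dpi against control (7, 13, 20, 6 and 10 with the preset), 1 for 14 against 3 dpi (11), and 0 for 30 against 14 dpi (8) and 100 against 30 dpi (7). The genes called for 14 against 3 dpi, 0 as reported, were 7 with pseudocount 10, 32 with no filter, 1 in the FPKM table, 92 with DESeq2 and 1 after thinning. For 3 dpi against control (33) there were 74 with no filter, 17 in the FPKM table, 19 with edgeR, 412 with DESeq2, 109 with the length trend removed and 19 after thinning. For 3 dpi against sham (96) there were 40 in the FPKM table, 585 with DESeq2 and 202 with the length trend removed. For 14 dpi against control (88) there were 58 in the FPKM table and 386 with DESeq2. DESeq2 also gave 29 genes for sham against control (0), 245 for 14 dpi against sham (73), 1130 for 100 dpi against sham (706), 775 for 30 against 14 dpi (393) and 381 for 100 against 30 dpi (76). With only the 2 groups compared in the fit, and so fewer samples for the spread, there were 0 for 3 dpi and 405 for 30 dpi against control, 11, 42 and 281 for 3, 14 and 30 dpi against sham, 177 for 30 against 14 dpi and 0 for 100 against 30 dpi. With the length trend removed there were 497 genes for 30 dpi against control (1120), 337 against sham (717) and 214 for 30 against 14 dpi (393), and 1 list for 30 dpi against control (6) and 14 for 30 against 14 dpi (8).

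Leaving out 1 library at a time, which also lowers the number of samples, gave these lowest and highest counts of genes over 6 fits: 0 to 6 for sham against control; 1 to 87, 5 to 60, 592 to 1414 and 588 to 806 for 3, 14, 30 and 100 dpi against control; 2 to 122, 11 to 53, 379 to 906 and 348 to 506 for the same times against sham. The steps gave 0 to 1 for 14 against 3 dpi, 142 to 482 for 30 against 14 dpi and 0 to 360 for 100 against 30 dpi. Lists moved were 7 to 10 for sham, 12 to 15 for 3 dpi, 14 to 20 for 14 dpi, 2 to 6 for 30 dpi and 7 to 11 for 100 dpi against control, then 11 to 12, 7 to 13 and 3 to 10 for the 3 steps.

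The replicate numbers are shared by all groups but the labels do not say that they pair the animals. Over 45 pairs of same-numbered libraries the correlation of deviations lay between -0.179 and 0.23, with 5 over 0.1, and 5 of the 18 libraries correlated best with their own number. Pairing over all groups was thus not seen, but some same-numbered libraries may share more than a number. Sham 3 correlated with 3 dpi 3 at 0.23 and with 100 dpi 3 at 0.147, and the latter 2 at 0.126. These are the libraries high in mitosis transcripts. With the replicate number as a block there were 16 and 52 genes for 3 and 14 dpi against control, 50 for 3 dpi against sham and 10 for 100 against 30 dpi. The other counts under the block stayed within 1.5 times, and it ended 4 list calls at 14 dpi against control, of macrophage, protease, antioxidant and TGF-beta genes (adjusted p from 0.0536 to 0.0631).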

Other observations

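The rows were also grouped by the stem of their symbol, with 113 families of at least 10 tested members, a grouping chosen after seeing the data. Families given here are some of those with a camera adjusted p under 0.05 at the preset correlation, and none of them held with an estimated one. At 14 dpi against control the Mcm family, which holds the replicative helicase subunits, had a median log2 change of 1.57 with 10 of 10 members above 0 and 0 called (camera adjusted p = 0.00064; adjusted p = 0.419 with an estimated correlation). From 14 to 30 dpi it had a median of -1.84 with 4 members called lower (adjusted p = 0.000158; adjusted p = 0.53 with an estimated correlation). At 30 dpi against control the mitochondrial ribosomal proteins of the Mrpl family had a median of -0.35 with 6 of 25 called lower (adjusted p = 1.35e-05; adjusted p = 0.478 with an estimated correlation). The Exosc family, subunits of the RNA exosome, had a median of -0.44 with 5 of 10 called lower (adjusted p = 0.00141; adjusted p = 0.366 with an estimated correlation). The Dennd family of Rab exchange factors had a median of 0.34 with 6 of 14 called higher (adjusted p = 0.00309; adjusted p = 0.366 with an estimated correlation).

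At 100 dpi against control the Psmd family of proteasome regulatory subunits had a median of -0.34 with 8 of 14 called lower (adjusted p = 0.000115; adjusted p = 0.425 with an estimated correlation). The Eif family of translation initiation factors had a median of -0.26 with 14 of 46 called lower and 1 higher (adjusted p = 7.04e-05; adjusted p = 0.517 with an estimated correlation). The Kif family of kinesin motors had a median of 0.60 with 7 of 23 called higher and 1 lower (adjusted p = 0.00222; adjusted p = 0.414 with an estimated correlation). The Dennd family had a median of 0.33 with 6 of 14 called higher (adjusted p = 0.00858; adjusted p = 0.414 with an estimated correlation). Long transcripts were higher and short ones lower at 30 and 100 dpi (Spearman's rho across genes 0.461 and 0.279), and families were not tested with that trend removed.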
